A study of Mus musculus with 17 samples.

How the data were processed

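Gene expression was measured by RNA sequencing in 17 libraries of B cells sorted by flow cytometry from mouse spleen. Per the labels' protocols, RNA was extracted with a kit for small samples, full-length cDNA was amplified by a SMART-Seq protocol from very low input (a fixed small mass, or part of the sample where RNA was too scarce to quantify), and libraries were made with a transposase kit and sequenced as read pairs. The labels' protocols name no molecular identifiers, so amplified copies of 1 molecule can be counted more than once, and count intervals and floors cover counting error only. The sorting gates, the strand setting, the treatment of reads with several matches and the annotation release are not given in the sources used here.

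The deposited file is a table of raw counts per gene, made by the authors with HISAT2 2.1.0, SAMtools 1.8 and featureCounts of Subread 1.6.2 on the mouse build GRCm38, per the submitters' processing notes. The deposited counts are whole numbers with no normalization by the authors that the values show. All 55536 gene identifiers matched GENCODE mouse release 21 on GRCm38, from which symbols, coordinates and gene types were taken. Column totals ran from 4067281 to 10036347 counts. Reads that near-identical genes share, such as those of the immunoglobulin constant regions, Pilrb1 and Pilrb2, Hba-a1 and Hba-a2, or a pseudogene and its parent, can be split or lost in such a table, and the values of these genes are uncertain for that reason. Overlapping and antisense genes cannot be told apart where strand was not used.

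Groups came from genotype and cell population in the labels: 3 libraries each of wild-type (WT) naive, activated and germinal centre (GC) B cells, 3 each of knock-in (p52ki) naive and activated cells, and 2 of p52ki GC cells. The replicate numbers are 1, 3 and 4 in WT and 2, 3 and 5 in p52ki, with 2 and 5 only in p52ki GC cells. The library numbers that end the sample titles run from 1 to 12 in WT and from 19 to 30 in p52ki. A batch that follows this order could not be told apart from genotype in any comparison of p52ki with WT. No label says that the replicates came from separate animals, so the p-values measure the spread between these samples, pooled over all groups. Libraries of the same group differed from each other by more than counting error in all pairs, with a chi-square per degree of freedom of 7.89 to 116 over genes, so none was treated as a repeat of another.

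Genes were kept by edgeR's filterByExpr over the 6 groups, which left 15352 of 55536. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest). The model had 1 coefficient per group over all 17 libraries, so that the 6 groups share an estimate of the spread. Rank correlation between libraries of a group was as low as 0.766 in GC cells and at least 0.935 in naive and activated cells. The shared spread may thus be too small for GC cells and too large for naive cells. There were 9 contrasts: p52ki against WT in naive, activated and GC cells, activated against naive and GC against activated in each genotype, and the difference of each stage change between genotypes. Unless another tool is named, an adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested in that contrast, and a gene was called at an adjusted p under 0.05. Values per gene are CPM, that is counts scaled to a common library total, means ± SD with n equal to the number of libraries, and log2 fold changes with their standard error (SE). Where every library of a group had no count, the fold is a bound computed from 3 counts summed over that group. Such a bound does not cover loss of transcripts before counting.

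A set of 35 gene lists was written before the data were examined, covering B cell states, NF-kB and ETS genes, the cell cycle, metabolism, signalling and stress, and markers of other cell types; 33 had at least 5 tested genes. They were tested with camera in limma 3.58.1, with the correlation between genes preset at 0.01 and, as an alternative, estimated from the data, and with fry, with Benjamini-Hochberg adjustment over the lists of a contrast. Genes to be named were also fixed before the data were examined: NF-kB subunits, Ets1 and a set of GC regulators in every contrast, of which some are not reported here. In each genotype or stage contrast up to 10 higher and 10 lower called genes with the largest change were added, with a mean of at least 5 CPM in a group compared and, between genotypes, no overlap of libraries. Up to 4 members with the smallest p were taken from each list, and the 5 with the smallest p where none passed. Variable gene segments, predicted genes and sex-linked control genes were left out of this naming but not of the tests, and those named in the text were chosen after their values were seen. Shares of immunoglobulin heavy constant counts were compared with exact two-sided permutation tests.

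The procedure was tested on simulated counts with 200 changed genes among 15352, drawn with the group means and totals of the real libraries. The simulated spread was 1 value per gene shared by all groups, and no simulated library was made to lose genes. The wrong calls below therefore do not show what GC libraries with few detected genes cause. The shares of changes called rest on that same spread. They may be too low for naive cells and too high for GC cells. For p52ki against WT in GC cells it called 1.59% of the changes of 2-fold, 30.5% of 4-fold and 52.7% of 8-fold, with 1 wrong call, and 2 of 33 unchanged lists. For activated cells it called 2.9%, 35.5% and 58% at the same sizes with 0 wrong calls, and for naive cells 1.43%, 38.1% and 58.2% with 5 wrong calls. For the difference of the GC change between genotypes it called 0 of 67 changes of 2-fold, 2.78% of 4-fold and 9.84% of 8-fold.

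Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, limma voom with a random effect per replicate number, no filter, a mean of at least 5 CPM, removal of immunoglobulin and T cell receptor genes, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were the 3 GC libraries with the fewest detected genes alone, the number of detected genes as a covariate, genes with a mean of at least 100 CPM alone, the mean of the naive and activated genotype contrasts, counts of called list members without WT GC replicate 3, the block for gene lists, and for lists in GC cells the covariate with an estimated correlation or without WT GC replicate 3. No column of the table was left unmapped.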

Results

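RNA was sequenced from naive, activated and germinal centre B cells of the mouse spleen. Naive B cells have not met antigen, and germinal centres (GCs) are the sites where activated B cells divide, mutate their antibody genes and are selected. The mice were wild type (WT) or carried a knock-in of p52 (p52ki), the NF-kB subunit made from the Nfkb2 gene; the series title concerns a complex of p52 with the transcription factor ETS1 in the formation of GCs. There were 17 libraries in 6 groups, 3 per group except for 2 of p52ki GC cells. Counts assigned to genes totalled 8113977, 7836022 and 7780482 in WT naive replicates 1, 3 and 4. They totalled 6211583, 8553748 and 8599156 in WT activated cells and 7625940, 4926763 and 9936589 in WT GC cells. In p52ki replicates 2, 3 and 5 they totalled 8592865, 8208782 and 9848870 in naive cells and 10036347, 8857512 and 8029313 in activated cells. The p52ki GC replicates 2 and 5 had 4067281 and 6625399.

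Nfkb2 (ENSMUSG00000025225, chromosome 19, 46304320 to 46312385 on GRCm38) was read in every library. It was at 138, 147 and 177 CPM in WT naive replicates 1, 3 and 4, and at 168, 129 and 207 in p52ki naive replicates 2, 3 and 5. In activated cells it was at 80, 149 and 98.9 in WT and 132, 109 and 120 in p52ki. In GC cells WT had 63.2, 41.7 and 58.4 CPM, and p52ki replicates 2 and 5 had 120 and 74. A knock-in keeps the gene, so these levels do not check the genotype labels. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the p52ki minus WT log2 difference of Nfkb2 was 0.13 in both naive and activated cells (SE 0.272, adjusted p = 1). It was 0.83 in GC cells (SE 0.302, adjusted p = 0.073). Ets1 (ENSMUSG00000032035, chromosome 9, 32636221 to 32757820) differed by 0.01, 0.26 and -0.07 in the same order, with adjusted p of 1, 1 and 0.897. Xist, which silences an X chromosome in female cells, was at 407 to 1180 CPM in the 17 libraries. Ddx3y, Eif2s3y, Kdm5d and Uty of the Y chromosome had 0 counts in all of them.

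The number of genes with at least 1 count separated the GC libraries. WT GC replicates 1 and 4 had 18449 and 19135 detected genes, whereas WT GC replicate 3 had 11232 and p52ki GC replicates 2 and 5 had 11390 and 13044. The other 12 libraries had 16745 to 19672. Thinned to the smallest library, the 3 sparse GC libraries had 11145, 11390 and 12740 genes, and WT GC replicates 1 and 4 had 17297 and 17389. Ribosomal protein genes took 5.38%, 6.32% and 5.07% of counts in the 3 sparse libraries, against 2.6% and 3.3% in WT GC replicates 1 and 4. Rank correlation of gene levels was 0.975 between WT GC replicates 1 and 4, 0.766 between the 2 p52ki GC libraries, and 0.792 and 0.814 between WT GC replicate 3 and replicates 1 and 4.

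**Figure D1:**
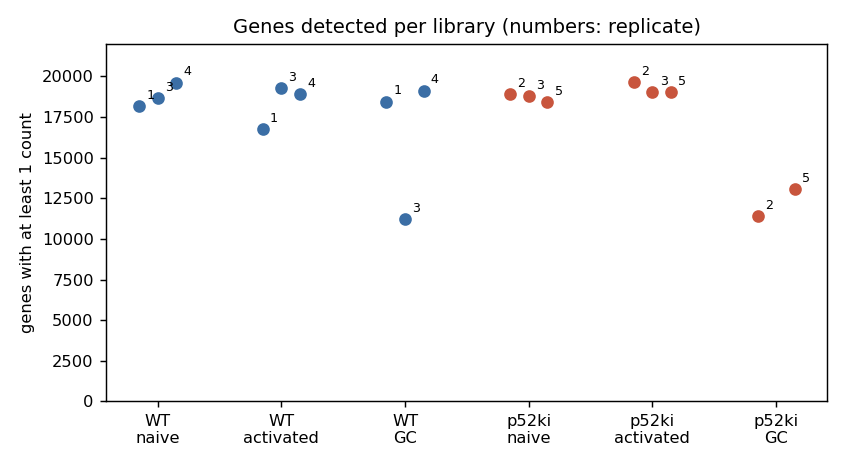
Genes with at least 1 count (vertical axis, number of genes) in each of the 17 libraries, 1 point per library labelled with its replicate number, by group. WT GC replicate 3 (11232) and both p52ki GC libraries (11390 and 13044) lie below the other 14, which have 16745 to 19672.

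Activated WT B cells were compared with naive WT cells to describe the first stage change. Ighg1, the IgG1 heavy chain constant region, went from 10.7 ± 6.46 to 4010 ± 3860 CPM (SD, n = 3 and 3; log2 8.55, SE 0.831, adjusted p = 0.000202). Jchain, which joins IgM and IgA into polymers, went from 16.4 ± 8.03 to 4350 ± 2920 (log2 8.04, SE 0.738, adjusted p = 0.000202). Of 8 heavy chain constant regions 5 rose and Ighd fell (log2 -1.9, SE 0.282, adjusted p = 0.00591). Mki67, a proliferation marker, rose by 2.7 on the log2 scale (SE 0.455, adjusted p = 0.0166). Fcer2a, which encodes CD23 of follicular B cells, fell by 1.52 on the log2 scale (SE 0.208, adjusted p = 0.0034), the chemokine receptor Ccr6 by 1.79 (SE 0.312, adjusted p = 0.0185) and Lmo2 by 1.22 (SE 0.158, adjusted p = 0.00307). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 49 genes were called, 39 higher and 10 lower in activated cells.

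By gene list, 5 of 8 heavy constant regions were higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 9.27e-27, and 0.00198 with an estimated correlation). Of 24 plasma cell and secretion genes 4 were higher, among them Derl3 (log2 3.21) and Edem1 (1.43) of protein quality control (12 adjusted over the list alone; camera adjusted p = 1.34e-25, adjusted p = 0.00673 with an estimated correlation). The marginal zone and B-1 list, markers of innate-like B cells, had a median log2 change of 1.9 with 0 of 20 members called over all genes and 13 higher adjusted over the list alone (camera adjusted p = 2.94e-24, adjusted p = 7.9e-05 with an estimated correlation). Its leading members were Cd9 (log2 2.62, adjusted p = 0.0529) and S1pr3 (log2 1.92, adjusted p = 0.062). For G2 and M phase 4 of 51 were higher (21 adjusted over the list alone) and for dark zone genes 3 of 20 (10), with adjusted p = 0.0359 and adjusted p = 0.0165 with an estimated correlation. Of 22 naive follicular genes 2 were lower and 0 higher (9 and 2 adjusted over the list alone; adjusted p = 0.000365 with an estimated correlation). Migration receptors had 1 of 20 lower (4 lower and 2 higher adjusted over the list alone; adjusted p = 0.0402 with an estimated correlation). The markers of macrophages, monocytes and dendritic cells summed to 762 ± 136 CPM against 434 ± 42.7, and T cell markers to 94.7 ± 29.9 against 60.9 ± 3.46. Both lists passed camera (adjusted p = 0.000178 and 5.86e-05), with adjusted p = 0.0783 and adjusted p = 0.178 with an estimated correlation. In place of 49 genes DESeq2 called 298, limma voom with quality weights 1618, a fit of the groups compared alone 332, no filter 120 and removal of the immunoglobulin genes 14. It was 14, 11 and 12 without WT naive replicate 1, 3 or 4, and 25 and 20 without WT activated replicate 1 or 4.

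GC cells of WT mice were then compared with activated WT cells. Bcl6, the master repressor of GC B cells, rose from 16.4 ± 4.97 to 99.2 ± 34.5 CPM (SD, n = 3 and 3; log2 2.59, SE 0.333, adjusted p = 0.000149). S1pr2, which keeps cells in the GC, rose by 5.38 on the log2 scale (SE 0.653, adjusted p = 0.000105). Mki67 rose from 22.3 ± 3.09 to 388 ± 71.7 CPM (log2 4.12, SE 0.462, adjusted p = 5.7e-05). Ccr7, the lymph node homing receptor, fell by 4.62 on the log2 scale (SE 0.387, adjusted p = 1.02e-05). Irf4, Myc and Nfkb2 fell by 2.03, 1.79 and 1.01 on the log2 scale (adjusted p = 0.000206, 0.0287 and 0.0244). The scavenging chemokine receptor Ackr3, at 21.2 ± 3.04 CPM in activated cells, had no count in any GC library and was at least 155-fold lower.

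By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2081 genes differed, 891 higher and 1190 lower in GC cells. Of 51 G2 and M phase genes 41 were higher and of 40 S phase genes 33 (49 and 37 adjusted over the list alone), with 0 lower in both; Kif23 rose by 3.63, Aurkb by 2.92 and Pcna by 1.83 on the log2 scale. Dark zone genes had 16 higher and 1 lower of 20 (18 and 1 adjusted over the list alone), and GC identity genes 16 higher and 1 lower of 24 (17 and 1). Lower were 15 of 22 naive follicular genes (16 adjusted over the list alone), 11 of 18 memory genes (13) and 10 of 20 migration receptors (12), each list also having 1 member higher by either adjustment. Lower too, with 0 higher, were 12 of 20 marginal zone and B-1 genes (15) and 16 of 28 type I interferon response genes (23). Examples were Hhex (log2 -3.88), a regulator of memory B cells, Cd1d1 (-4.61), S1pr1 (-4.33) and the antiviral gene Mx1 (-5.2). These 9 lists passed camera with an estimated correlation, with adjusted p from 6.32e-05 for the naive list to 0.00647 for S phase. Cholesterol synthesis had 9 of 22 higher (14 adjusted over the list alone), including Idi1 (log2 2.28), and hypermutation and DNA repair 11 of 28 (16), including Hmces (3.62), with adjusted p = 0.192 and adjusted p = 0.105 with an estimated correlation. Marginal zone and B-1 markers summed to 528 ± 171 CPM in WT GC against 3287 ± 226 in activated cells. RLE scaling moved the median of all genes by -0.1 on the log2 scale, and 2144 genes were then called. A fit of the groups compared alone called 543, DESeq2 3339 and limma voom with quality weights 5023, and without WT activated replicate 4 the count was 1308.

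**Figure D2:**
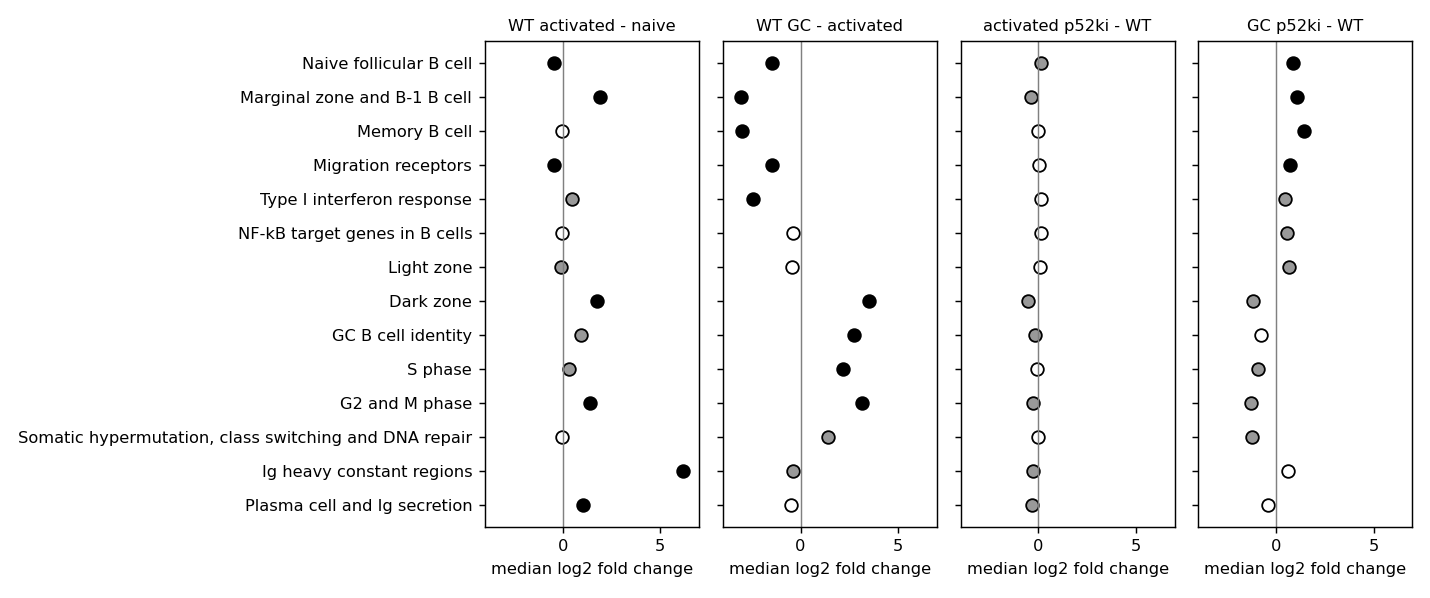
Median log2 fold change of the members of 14 gene lists (horizontal axis) in 4 contrasts, 1 point per list. Black points passed camera with the preset and the estimated correlation, grey points with the preset alone and open points with neither; the naive, marginal zone, memory and migration lists are black at 0.87, 1.06, 1.41 and 0.68 in p52ki against WT GC cells.

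Naive p52ki and WT cells were compared for differences before activation. Of the NF-kB subunits, Nfkb1 was at 82.1 ± 2.9 CPM in WT and 102 ± 6.99 in p52ki (SD, n = 3 and 3; log2 0.31, SE 0.256, adjusted p = 1), and Rela at 158 ± 4.26 and 157 ± 17.9. Ighg1, of which naive cells hold little, was at 10.7 ± 6.46 CPM in WT and 1.52 ± 0.582 in p52ki (log2 -2.79, SE 0.736, adjusted p = 1). Mid1, of the X chromosome, was at 5.22 ± 3.11 and 0.481 ± 0.475 (log2 -3.37, SE 0.951, adjusted p = 1). Over all stages Mid1 was at 2.79 to 38.3 CPM in the WT libraries and at 0 to 1.32 in the p52ki libraries, without overlap. Immediate early genes, which dissociation and stimulation induce, had a median log2 difference of 0.27 with 22 of 23 positive and 0 called, over all genes or adjusted over the list alone (camera adjusted p = 1.05e-05, adjusted p = 0.951 with an estimated correlation). NK cell markers had a median of 0.77 with 0 of 11 called and summed to 29.3 ± 5.29 CPM in p52ki and 18 ± 6.1 in WT (camera adjusted p = 0.000133, adjusted p = 0.614 with an estimated correlation). No gene was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 15352 genes 80 had an unadjusted p under 0.05, fewer than that threshold gives with no difference at all. The test, with a spread shared by 6 groups, was thus conservative in naive cells. The 0 calls therefore do not show that no gene differs. DESeq2 called 5, limma voom with quality weights 13, limma voom with a random effect 3, a fit of these groups alone 13 and no filter 4. Of 5 lists that passed camera, 0 passed with an estimated correlation, and the number was 2 without WT naive replicate 1 or 3, 3 without p52ki naive replicate 2 and 8 without p52ki naive replicate 3 or 5. For the erythroid and platelet list the median was -0.14 although camera's direction was higher in p52ki (adjusted p = 0.0439, adjusted p = 0.951 with an estimated correlation).

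Activated p52ki and WT cells were compared next. Ighg1 (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523) was at 4010 ± 3860 CPM in WT and 189 ± 107 in p52ki (SD, n = 3 and 3; log2 -4.41, SE 0.684). Without WT activated replicate 4, at 8410 CPM against 2450 and 1180 in the other WT libraries, the log2 difference was -3.26 (adjusted p = 0.127). Ighg1 was lower in 3 of 3 p52ki libraries than in any WT library but missed the threshold, with an adjusted p of 0.0541. It passed with DESeq2 (adjusted p = 6.77e-08), with limma voom with quality weights (4.04e-05), without WT activated replicate 3 (0.0132) and with the number of detected genes as a covariate (0.0437), the last chosen after seeing the data. Its adjusted p ran up to 0.824 without p52ki activated replicate 3. As a share of heavy chain constant counts Ighg1 took 14.1% ± 8.88 in WT and 1.03% ± 0.61 in p52ki, and Igha 0.763% ± 0.519 and 2.65% ± 0.671. Both gave p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 can give. Ighg3, Ighe and the lambda light chain constant region Iglc1 had log2 differences of -2.04, -4.97 and -1.83 (adjusted p = 1 for each). Ighv1-72, a variable segment known from the C57BL/6 response to the hapten NP and named after its values were seen, was at 478 ± 372 CPM in WT and 41.7 ± 7.43 in p52ki (log2 -3.52, SE 0.468, adjusted p = 0.0266).

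Ighv1-72 was 1 of 2 genes called in activated cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other was Gm42031, a long noncoding RNA also named after its values were seen, at 3.94 ± 2.33 CPM in WT and 92.9 ± 71.2 in p52ki (log2 4.53, SE 0.666, adjusted p = 0.0433). Of 8 heavy constant regions 0 were called over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 3.03e-06, adjusted p = 0.248 with an estimated correlation). Plasma cell and secretion genes had 0 of 24 called by either adjustment and a median log2 difference of -0.35 (camera adjusted p = 1.52e-06, adjusted p = 0.274 with an estimated correlation). G2 and M phase genes had 0 of 51 called by either adjustment and a median of -0.28 (camera adjusted p = 7.11e-07, adjusted p = 0.402 with an estimated correlation). NK cell markers had a median of 0.54 and erythroid and platelet markers of 0.09 (camera adjusted p = 0.00966 and 0.00943), with adjusted p = 0.521 for both with an estimated correlation. Of 12 lists that passed camera 0 passed with an estimated correlation, and the erythroid and platelet list had 1 member higher adjusted over the list alone. The 2 calls became 0 without WT activated replicate 1 or any of the 3 p52ki activated libraries and 1 without WT activated replicate 4. DESeq2 called 9, limma voom with quality weights 43, no filter 5 and removal of the immunoglobulin genes 0. Of 15352 genes 134 had an unadjusted p under 0.05 by edgeR's test, fewer than that threshold gives with no difference. The test was thus conservative here too.

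**Figure D3:**
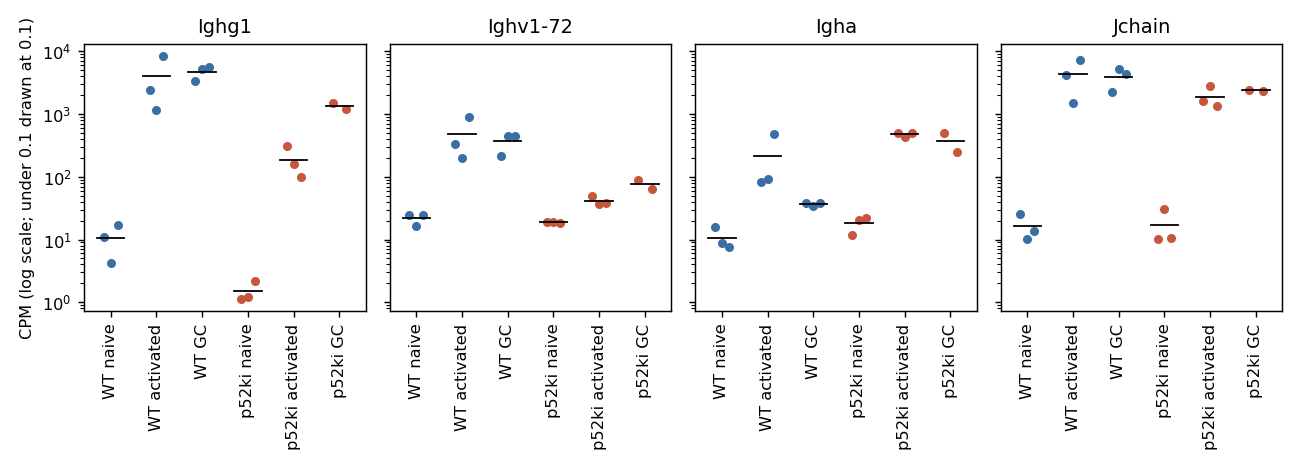
CPM (vertical axis, log scale) of Ighg1, Ighv1-72, Igha and Jchain in each library, 1 point per library, with a bar at the group mean. Ighg1 averages 4010 in WT and 189 in p52ki activated cells, and 4750 and 1340 in GC cells; the p52ki GC group has 2 libraries.

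GC cells were compared between genotypes. Ccr7, a chemokine receptor, was at 13.8 ± 6.07 CPM in WT and 132 ± 62.3 in p52ki (SD, n = 3 and 2; log2 3.25, SE 0.384, adjusted p = 0.000105). Hhex was at 14.6 ± 4.04 and 53 ± 1.83 (log2 1.85, SE 0.211, adjusted p = 7.37e-05), and the survival gene Bcl2 at 4.01 ± 3.97 and 35.8 ± 11.7 (log2 3.09, SE 0.69, adjusted p = 0.00985). Kif23, a kinesin of cell division, was lower at log2 -1.75 (SE 0.321, adjusted p = 0.00282), as were Hjurp at -2.69 (SE 0.365, adjusted p = 0.000271) and Rrm1 at -2.77 (SE 0.554, adjusted p = 0.00523). Irf4 was higher, at 34.9 ± 7.92 against 17.9 ± 5.57 CPM (log2 0.97, SE 0.295, adjusted p = 0.0383). Prdm1, the plasma cell regulator, had 9.98 ± 7.02 CPM in WT and no count in either p52ki library, at least 34-fold lower (adjusted p = 0.00751). Bcl6 was at 99.2 ± 34.5 and 81.5 ± 11.1 CPM (adjusted p = 0.609). Mki67 was at 388 ± 71.7 and 172 ± 70.2 (log2 -1.17, adjusted p = 0.0988).

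By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2450 genes differed in GC cells, 575 higher and 1875 lower in p52ki. A fit of the 5 GC libraries alone called 0 and limma voom with quality weights 15, while DESeq2 called 3924. The spread shared by all groups may be too small for GC cells, so SEs and p-values in this contrast may be too small. The count was 4406 without WT GC replicate 3, 4472 without p52ki GC replicate 5 and 1561 without WT GC replicate 1. Both p52ki libraries and WT GC replicate 3 are the libraries with few detected genes, and 851 of the 1875 lower genes had no count in either p52ki library. Against WT GC replicate 3 alone, a comparison chosen after seeing the data, 3901 genes were called, 2590 higher and 1311 lower in p52ki, with that lone WT library assumed to vary like the other groups. Among genes with a mean of at least 100 CPM, 307 of 1966 were called, 120 higher and 187 lower. The largest lower changes all had no count in p52ki, among them Hacd3 (45.7 ± 13.6 CPM in WT, at least 156-fold), Ice2 (37.2 ± 9.2, at least 127-fold) and Cpt2 of mitochondrial fatty acid import (29.9 ± 7.26, at least 102-fold). These bounds cover counting error only, not loss of transcripts in libraries with few detected genes. The largest higher changes included Ifitm1 (at least 57.1-fold, with no count in WT), Mx1 (log2 6.29, SE 0.765), the cytokine gene Il18 (5.65, SE 0.865) and Nr4a3 (5.63, SE 1.45).

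Of 22 naive follicular genes 9 were higher in p52ki GC cells and 1 lower (10 and 1 adjusted over the list alone), including Klf2 (log2 1.74). Of 20 marginal zone and B-1 genes 6 were higher and 1 lower (7 and 1), including Cd9 (3.06), Plac8 (3) and the complement receptor Cr2 (1.44), and of 18 memory genes 6 were higher and 0 lower (7 and 0). Of 20 migration receptors 5 were higher and 1 lower (5 and 2 adjusted over the list alone), including Gpr183 (1.41). These 4 lists passed camera with an estimated correlation (adjusted p = 0.0033, 0.0397, 0.0243 and 0.0319). Against WT GC replicate 3 alone, a single library assumed to vary like the other groups, the memory list had a median log2 difference of 3.22 (camera adjusted p = 0.000191). The naive, marginal zone and migration lists had medians of 0.76, 1.06 and 0.73 (camera adjusted p = 0.0851, 0.297 and 0.327). The marginal zone and B-1 markers summed to 1780 and 1240 CPM in the p52ki GC libraries against 427, 726 and 431 in WT GC replicates 1, 3 and 4.

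Of 51 G2 and M phase genes 15 were lower and 0 higher (19 and 0 adjusted over the list alone), and of 40 S phase genes 11 and 0 (14 and 0). For these lists camera gave adjusted p of 7.67e-07 and 0.000441, with adjusted p = 0.366 and adjusted p = 0.599 with an estimated correlation. Hypermutation and DNA repair genes had 7 of 28 lower (7 adjusted over the list alone), dark zone genes 2 of 20 (1) and cholesterol synthesis genes 5 of 22 (6), with adjusted p = 0.706, 0.592 and 0.728 with an estimated correlation. Type I interferon response genes had 8 of 28 higher and 1 lower (8 and 2 adjusted over the list alone), including Oasl1 (log2 2.57) and Trim30a (1.17), with adjusted p = 0.0737 with an estimated correlation. The median of this list was 0.47, and in alternatives chosen after seeing the data it was 1.63 against WT GC replicate 3 alone (camera adjusted p = 0.027) and 1.29 with the number of detected genes as a covariate (0.00312). Light zone genes had 6 of 22 higher and 1 lower (9 and 1 adjusted over the list alone), among them Nfkbia (1.38) and Egr3 (3.1), and NF-kB targets 3 of 36 higher and 2 lower (3 and 2), with adjusted p = 0.0737 and adjusted p = 0.0897 with an estimated correlation. MHC class II presentation had 2 of 14 higher (4 adjusted over the list alone), Ctss (1.09) and Ifi30 (1.25), and immediate early genes 3 of 23 (3), with adjusted p = 0.47 and adjusted p = 0.728 with an estimated correlation. All 14 lists passed with the preset correlation, and without p52ki GC replicate 2 the number that passed was 8. Against WT GC replicate 3 alone it was 3.

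Isotype shares were also compared in GC cells. Ighg1 took 41.8% ± 4.43 of heavy constant counts in WT and 12.1% ± 1.83 in p52ki (SD, n = 3 and 2; exact two-sided permutation test, p = 0.1, the smallest these libraries allow). Ighm took 46.1% ± 4.41 and 67.2% ± 9.17 (exact p = 0.1), and Igha 0.345% ± 0.114 and 3.41% ± 1.6 (exact p = 0.1). In the gene test Igha was higher in p52ki (log2 3.35, SE 0.604, adjusted p = 0.00261), Ighd was higher (log2 1.37, SE 0.303, adjusted p = 0.00915), and Ighg1 had a log2 difference of -1.83 (SE 0.711, adjusted p = 0.0893). Ighv1-72 was lower in p52ki GC cells, at 76.3 ± 18.8 against 372 ± 134 CPM (log2 -2.29, SE 0.52, adjusted p = 0.0106).

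Markers of other cell types were counted in the same contrast. Of 17 T cell markers 2 were higher and 3 lower, of 11 NK cell markers 1 and 1, of 23 macrophage, monocyte and dendritic cell markers 1 and 4, of 5 follicular helper markers 1 and 0, and of 9 erythroid and platelet markers 0 and 0. Adjusted over the list alone the counts were the same. Camera gave these lists adjusted p of 0.702, 0.451, 0.603, 0.417 and 0.247, and its direction was higher for the macrophage and follicular helper lists although their medians were -0.33 and -0.47, both 0 with genes lacking a count in a group set at their bound. Erythroid and platelet markers summed to 406 ± 35.4 CPM in p52ki GC cells and 180 ± 112 in WT GC cells. Stromal and follicular dendritic cell markers summed to 409 and 316 CPM in p52ki GC replicates 2 and 5 and to 175, 150 and 194 in WT, mostly from Vim and Pecam1, which were at 197 and 182 CPM in WT naive B cells.

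Activation and GC entry were also followed within p52ki. From naive to activated cells 18 genes were called, 13 higher and 5 lower, among them Jchain (log2 6.8, SE 0.699, adjusted p = 0.00102) and Ighg1 (6.92, SE 0.811, adjusted p = 0.00276). DESeq2 called 152, limma voom with quality weights 1228, a fit of these groups alone 467, no filter 41 and removal of the immunoglobulin genes 1. It was 1 without p52ki naive replicate 2 or 3, 3 without naive replicate 5 or activated replicate 2, and 6 without activated replicate 3. All 15 genes called in both genotypes at this step changed in the same direction. Of these 10 rose and 5 fell, where independent lists would share 0.033 higher and 0.00326 lower genes. The 2 contrasts use the same spread per gene, so they are not fully independent. From activated to GC cells 3930 genes were called in p52ki, 974 higher and 2956 lower, with Bcl6 at log2 2.16 (SE 0.349, adjusted p = 0.000824) and Mki67 at 3.55 (SE 0.472, adjusted p = 0.000205). Of the 1093 genes called in both genotypes at that step 1056 changed in the same direction, 411 higher and 645 lower. Independent lists would share 56.5 higher and 229 lower genes. Both contrasts use the same spread per gene and hold GC libraries with few detected genes, so loss of transcripts can add to the sharing. Over 10575 genes with a mean of at least 5 CPM the Pearson correlation of the 2 log2 changes was 0.415. With the number of detected genes as a covariate, an alternative chosen after seeing the data, 3170 were called in p52ki, 1959 higher and 1211 lower. Among genes with a mean of at least 100 CPM 285 were higher and 282 lower. The number called was 186 by limma voom with quality weights, of which 153 were higher and 33 lower, 1613 in a fit of these groups alone and 2482 without p52ki activated replicate 2.

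Whether a stage change differed between genotypes was tested directly. For the change from naive to activated cells 0 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 65 of 15352, fewer than that threshold gives with no difference, so the test was conservative. DESeq2 called 2 and limma voom with quality weights 0. The smallest p belonged to Ighg3 (log2 -2.55, SE 0.718, adjusted p = 1) and Slpi (-3.42, SE 1.13, adjusted p = 1). For the change from activated to GC cells 913 genes passed, 150 with a more positive and 763 with a more negative change in p52ki. The latter included Hacd3 (log2 -11.5, SE 0.87, adjusted p = 9.85e-06) and Prdm1 (-9.03, SE 2.17, adjusted p = 0.0289), fitted values that rest on libraries without a count. Bcl6 and Mki67 did not pass (log2 -0.44 and -0.57, adjusted p = 0.627 and 0.63). DESeq2 called 2243, limma voom with quality weights 13, and a fit of these groups alone 123. In alternatives chosen after seeing the data, the 3 sparse GC libraries alone gave 2928 genes, 1997 with a more positive and 931 with a more negative change in p52ki, and the number of detected genes as a covariate gave 2465, 1577 and 888. The count was 567 without WT GC replicate 1, 2810 without WT GC replicate 3 and 3121 without p52ki GC replicate 5. It was 445 and 427 without WT activated replicate 1 or 4, and 384, 531 and 494 without p52ki activated replicate 2, 3 or 5.

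**Figure D4:**
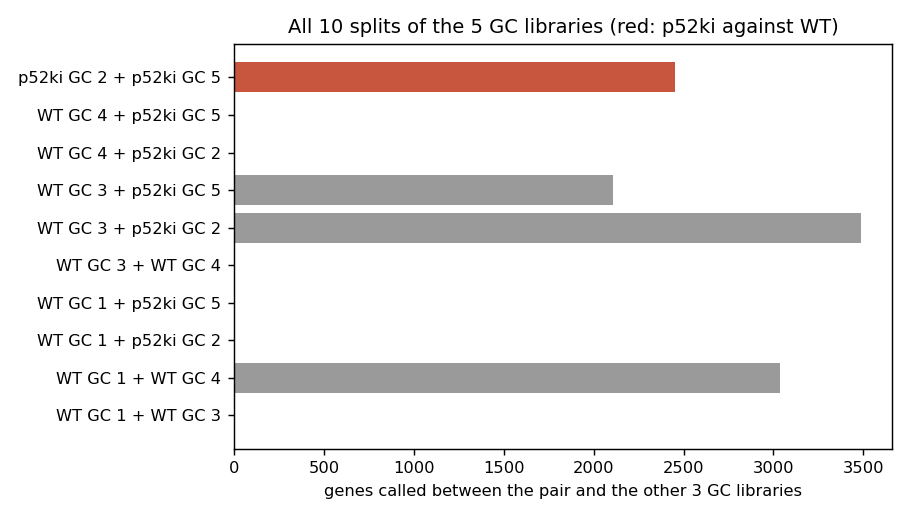
Number of genes called (horizontal axis) between each pair of GC libraries and the other 3, for all 10 splits of the 5 GC libraries; the red bar is p52ki against WT. The real split gave 2450 genes, WT GC replicate 3 with p52ki GC replicate 2 gave 3488, WT GC replicates 1 and 4 gave 3037, and WT GC replicate 3 with p52ki GC replicate 5 gave 2105.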

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

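The tests of single genes, those of lists by genotype with all libraries, and the number of lower genes in other splits of the GC libraries were fixed before their results were seen; the tests of lists on the difference between genotypes, and all other tests of explanations in this part, were not fixed then, the latter being chosen after the results they bear on were seen.

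The change from activated to GC cells differed between genotypes for 913 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and for 11 gene lists by camera. The naive, marginal zone and B-1, memory and migration lists fell less in p52ki, with camera adjusted p of 0.000223, 4.72e-05, 3.45e-06 and 0.00269. They kept adjusted p of 0.0249, 0.0279, 0.0279 and 0.0279 with an estimated correlation. The other 7 lists, among them S phase (camera adjusted p = 0.00515) and G2 and M phase (0.00269), had adjusted p of 0.167 to 0.808 with an estimated correlation. Among single genes, the macrophage receptor Mrc1 had a more positive change in p52ki (log2 6.68, adjusted p = 0.0378), and Hacd3 (log2 -11.5, adjusted p = 9.85e-06) a more negative one.

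Of the genes that differed by genotype in GC cells, 1875 were lower in p52ki, and loss of transcripts in libraries with few detected genes is a candidate explanation for many of these. When WT GC replicate 3 was grouped with p52ki GC replicate 2, 2980 genes were lower in that pair than in the other 3 libraries. Of 8672 genes at 10 CPM or more in WT GC replicates 1 and 4, 64 had no count in both p52ki libraries but a count in WT GC replicate 3, against 178 and 67 for WT GC replicate 3 paired with p52ki replicate 2 or 5. The pairs that mix genotypes thus lost as many genes as the p52ki pair, which the loss explanation needs. With genes at 0 in all 3 libraries counted in, the p52ki pair had 116 and the mixed pairs 230 and 119, where independent losses would give 29, 74 and 26, an excess in mixed pairs too that says nothing of genotype, whose effect on part of the 1875 stays open.

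The memory list was higher in p52ki GC cells, with a median log2 difference of 1.41. With the number of detected genes as a covariate the median was 2.37 (camera adjusted p = 7.05e-06, and 0.00738 with an estimated correlation). With the covariate and without WT GC replicate 3 it was 1.5 (camera adjusted p = 0.00387, and 0.08 with an estimated correlation). Against WT GC replicate 3 alone the median was 3.22, which rests on 1 WT library. That library also held 58.2% of the within-group variation in detected genes, so the covariate leans mostly on it. These fits therefore do not decide whether loss is the cause for the memory list. The naive and marginal zone lists also passed with the covariate (medians 0.86 and 1.33, adjusted p = 0.00298 and 0.0322) and with it and without WT GC replicate 3 (0.00913 and 0.00769), but had 0.0851 and 0.297 against that library alone and 0.0713 and 0.325 with the covariate and an estimated correlation, so loss stays open for them. The naive and marginal zone medians against that library alone were 0.76 (SE 0.21) and 1.06 (SE 1.1). With all libraries they were 0.87 and 1.06. The missed calls thus did not come with clearly smaller medians, but a fit with 1 WT library cannot exclude loss. In both p52ki GC libraries 8 genes of the 3 lists (Bcl2, Cr2, Plac8, Cd9, Bhlhe41, Ccr7, Asb2 and Hhex) exceeded every other GC library more than 2-fold. The same count was 0 for either pairing of WT GC replicate 3 with a p52ki library and 2 for WT GC replicates 1 and 4. Over 53 list genes the median log2 difference from WT GC replicates 1 and 4 was -0.38 (SE 0.31) in WT GC replicate 3 and 0.71 (SE 0.27) in p52ki, and neither this nor the 8 genes decides, since the lists were chosen for being higher and 1 WT library has few detected genes. B cells from outside the GC in the p52ki sort may also contribute, and both these and a GC cell state changed by genotype stay open: of 88 genes chosen as low in WT GC replicates 1 and 4, 89.8% and 83% lay above these in p52ki replicates 2 and 5 (77.3% in both) and 60.2% in WT GC replicate 3, with median outside shares of 23.1%, 21% and 4.05%.

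The median log2 change of S, G2 and M phase genes in p52ki GC cells was -1.17 (SE 0.07) over 91 genes. The outside share estimated from the same libraries, 22.1%, would give -0.31, so such cells alone may be too few. The median was also -0.88 in WT GC replicate 3 against WT GC replicates 1 and 4. The G2 and M phase list passed camera against WT GC replicate 3 alone (median -0.57, adjusted p = 0.027) and with the covariate (-0.72, adjusted p = 0.000667), but not with the covariate and without WT GC replicate 3 (-0.9, adjusted p = 0.391), and S phase had adjusted p of 0.576, 0.18 and 0.625. With all libraries and an estimated correlation neither list passed (adjusted p = 0.366 and 0.599). Library quality and slower division of p52ki GC cells therefore stay open. Dilution stays open as a part of the fall, its predicted -0.31 being smaller than the -1.17 seen.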

How the results depend on the processing

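The 3 sparse GC libraries alone, the number of detected genes as a covariate in any form, genes of at least 100 CPM alone and the block for gene lists were alternatives chosen after seeing the data; the others given here, each library left out included, were fixed before the data were examined. Unless a construction shows it, the cause of a change was not tested. Libraries of 4067281 to 10036347 counts and GC libraries with as few as 11232 detected genes limit what can be seen for genes of low level.

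For p52ki against WT in naive cells (0 genes by edgeR's quasi-likelihood test, 80 at an unadjusted p under 0.05), no filter gave 4 genes, DESeq2 5, limma voom with quality weights 13, the compared groups alone 13 and the covariate 4; leaving out a library gave 0 throughout. For activated cells (2), no filter gave 5, removal of immunoglobulin genes 0 (Ighv1-72 is such a gene, and the cause was not tested for Gm42031), DESeq2 9, quality weights 43, the covariate 5 and libraries left out 0 to 2. For GC cells (2450), DESeq2 gave 3924, quality weights 15, the compared groups alone 0, the sparse libraries alone 3901, the covariate 3679 (2295 higher and 1384 lower), genes of at least 100 CPM 338, fewer genes being tested, and libraries left out 1561 to 4472.

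For activated against naive cells in WT (49), no filter gave 120, removal of immunoglobulin genes 14, DESeq2 298, quality weights 1618, the compared groups alone 332 and libraries left out 11 to 52. In p52ki (18) the same settings gave 41, 1, 152, 1228, 467 and 1 to 12. For GC against activated cells in WT (2081), DESeq2 gave 3339, quality weights 5023, the compared groups alone 543, genes of at least 100 CPM 600 and libraries left out 1308 to 2636. In p52ki (3930) a mean of at least 5 CPM gave 2407, quality weights 186, the compared groups alone 1613 and libraries left out 2482 to 5436. For the difference of the activation change (0), DESeq2 gave 2. For that of the GC change (913), DESeq2 gave 2243, quality weights 13, the compared groups alone 123, the sparse libraries alone 2928, the covariate 2465 and libraries left out 384 to 3121.

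For gene lists, an estimated correlation left 0 of 5 in naive cells, 0 of 12 in activated cells and 4 of 14 in GC cells by genotype, and 7 of 19 and 9 of 19 for the WT stages. By fry 0, 0 and 16 differed by genotype and 10 and 25 by stage. The sparse libraries alone left 3 in GC cells, the covariate 6, the covariate with an estimated correlation 1, and the covariate without WT GC replicate 3 6. Libraries left out gave 2 to 8, 8 to 13 and 8 to 15 by genotype, and 17 to 21 and 15 to 20 by stage.

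Replicate numbers were tested as a pairing. Of 16 same-number pairs 4 correlated over 0.1, with a range of -0.229 to 0.281. All 4 were among the 6 naive and activated pairs, which ran from 0.079 to 0.281. Of these 6 pairs 5 correlated best with their own number. Library numbers also run in sequence within a replicate number, as 1, 2 and 3 for the naive, activated and GC cells of WT replicate 1. No label says that libraries of the same number share an animal, so this stays open. The main stage tests did not use such a pairing. The other pairs involve GC libraries, several of them with few detected genes, and cannot exclude a pairing. With the replicate number as a block the counts were 17 and 1272 for the WT stages, 2 and 2423 for the p52ki stages, and 0 and 271 for the differences between genotypes; with it as a random effect they were 3, 2 and 1890 for naive, activated and GC cells by genotype. Lists by stage were 21 and 19 with the block.

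Of the named genes' values under all settings, those of p52ki against WT GC cells kept their side of the threshold in 379 cases, lost it in 59, gained it in 19 and changed sign without passing in 21. In naive and activated cells by genotype 229 and 233 kept it, 3 and 8 gained it, and 19 and 10 changed sign without passing. Those of WT GC against activated cells kept it in 265 and lost it in 24, and those of WT activated against naive cells kept it in 183 and lost it in 77. For the difference of the GC change, 271 were kept, 135 lost and 3 reversed. With a library left out Cyp2d22 ran from -0.59 to 9.25 and Sspn from -2.11 to 9.38 on the log2 scale, each lowest without p52ki GC replicate 2. Cldn10 ran from -0.09, without p52ki GC replicate 5, to 8.57.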

Other observations

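The tests of single genes in the stage and genotype contrasts, of lists in WT stages, and the numbers of calls in other splits were fixed before their results were seen. The tests of lists in p52ki stages and on the difference between genotypes were not fixed then, and the tests of explanations and of naive and activated cells together were chosen after the results they bear on were seen.

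In WT cells Mx1 fell by 5.2 and Oasl1 by 3.83 on the log2 scale from activated to GC cells (adjusted p = 0.000239 and 3.9e-05). In p52ki 11 of 28 type I interferon response genes fell and 0 rose at the same step (12 and 0 adjusted over the list alone; camera adjusted p = 0.00336, adjusted p = 0.248 with an estimated correlation). Of 37 oxidative phosphorylation genes 17 were higher and 1 lower in GC than in activated p52ki cells (21 and 2 adjusted over the list alone; camera adjusted p = 1.23e-08, adjusted p = 0.465 with an estimated correlation). In WT 6 of 37 were higher (8 adjusted over the list alone; camera adjusted p = 2.42e-07, adjusted p = 0.395 with an estimated correlation), and the difference between genotypes did not pass (camera adjusted p = 0.165).

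Ighv1-72 was lower in activated p52ki cells, and Ighg1 and the lambda light chain gene Iglc1 lay on the same side without passing edgeR's test. An immunoglobulin haplotype from another strain is argued against as the whole cause for Ighv1-72, since in naive cells it differed by -0.21 on the log2 scale (95% interval -1.13 to 0.72), against -3.52 (-4.51 to -2.52) in activated cells. Of 55 heavy chain variable segments at 5 CPM or more in naive cells 0 differed by more than 1 on the log2 scale (median absolute difference 0.1), as did 0 of 83 kappa segments (0.13), which lie on another chromosome. For Ighg1, an equal loss of antibody-secreting cells of all isotypes from the activated gate is argued against as the whole cause. Jchain differed by -1.19 (95% interval -2.36 to -0.03), less than Ighg1 at -4.41 (-5.87 to -2.95), and Igha was not lower (1.14, 0.01 to 2.27). Jchain was itself lower, and plasma cell and secretion markers summed to 4773 ± 913 CPM in p52ki against 8047 ± 3750 in WT. This sum includes Jchain and is no separate evidence. Jchain was also at 2240 to 5270 CPM in WT GC cells, so it may not mark antibody-secreting cells alone. Fewer antibody-secreting cells may contribute, and a loss of IgG1-secreting cells alone was not tested. Ighv1-72 with a lambda light chain is the well-known receptor of the C57BL/6 response to NP, and a smaller response of that kind in p52ki stays a candidate explanation that was not tested, since the labels name no immunogen.

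The genotypes differed in 5 genes across naive and activated cells together, in a comparison chosen after seeing the data. This comparison treated naive and activated libraries as independent. The random effect per replicate number had a consensus correlation of -0.0424 over all stages. It therefore cannot allow for naive and activated libraries of the same number that vary together. Gm42031 was at 42.9 to 175 CPM in the 8 p52ki libraries and at 2 to 6.52 in the 9 WT libraries, GC cells included (log2 4.44, adjusted p = 0.00147, and 0.0529 by limma voom with a random effect). G530011O06Rik of the X chromosome differed by -6.26 (adjusted p = 0.0254, and 0.00153 with the random effect), and Gm21860 and Gm21748 by -8.05 and -7.99 (adjusted p = 0.0105 and 0.0121, and 0.000148 and 0.000171 with the random effect). The last 2 are annotated on the Y chromosome, from 90754513 and 90838869, and G530011O06Rik on the X chromosome from 169975043. Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 17 libraries, so these annotations do not show a Y chromosome in the cells. Whether these differences are separate effects of genotype or 1 linked difference between the mouse lines was not tested. G530011O06Rik, Gm21860 and Gm21748 had no count in any p52ki naive library, so their differences are fitted values and not bounds. Ighg1 differed by -3.6 (adjusted p = 0.0121, and 1 with the random effect).

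With 3 libraries against 3 or 3 against 2 there are 10 splits, too few for a share under 0.05. In naive cells the real split called 0 genes by edgeR's quasi-likelihood test, as did all 10 (highest other 0), with 80 at an unadjusted p under 0.05, 5 by DESeq2 and 13 by limma voom with quality weights. For its lists 6 of 10 splits reached the real 5, and the highest other was 10. In activated cells 1 split of 10 reached 2 genes (highest other 1), and 3 of 10 reached 12 lists (highest other 13). In GC cells 3 of 10 splits reached 2450 genes, with 3488 the highest, and the 4 splits with 2105 or more genes each set WT GC replicates 1 and 4 apart from at least 2 of the 3 libraries with few detected genes, which is a structure of the libraries. For WT activated against naive cells 1 split reached 49 genes (highest other 0) and 1 reached 19 lists (highest other 13). For WT GC against activated cells 1 reached 2081 genes (highest other 0) and 2 reached 19 lists (highest other 19). For p52ki activated against naive cells 1 reached 18 genes (highest other 0). For the difference of the activation change between genotypes all 60 drawn regroupings reached the real 0, as any count must, so they say nothing of chance (highest other 5).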
